A study of Homo sapiens with 6 samples.

How the data were processed

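Total RNA from 2 parental and 4 olaparib-resistant PEO1 samples was extracted with a column kit and made into TruSeq libraries, per the labels' protocols. Per the submitters' processing notes, HISAT2 2.1.0, bedtools, edgeR and the genome build GRCh37/hg19 were used; their roles are not given in the sources used here. The authors deposited 1 table of TPM values for 17872 gene symbols, per the file header. How reads were assigned to genes, how TPM were computed and whether strand was used are not given in the sources used here. The deposited TPM of a library add up to 293888 to 307895, less than the full TPM scale. Each library was matched to its sample by its title, and 0 columns were left unmapped.

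The table holds no exact 0; 9540 cells of 2941 genes have no value and were treated as 0 TPM. Of these genes 98.0% had a highest value under 1 TPM, and 838 genes had a value in 1 library. Symbols on 2 lines of the table (4 symbols) were kept as separate genes. WNT3A and the 13 mitochondrially encoded genes are not analysed here.

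TPM keep no read total, so depth is unknown and no counting intervals are given. Among genes with a mean below 0.3 TPM in P1 and another library, the commonest ratio of the other value to that in P1 was shared by 34 to 54 genes. Its inverse was taken as the relative depth of that library. Once divided by it, 12.6 to 14.3% of the ratios were ratios of whole numbers up to 20 within a tolerance of 1e-06. Most ratios were not of this kind, so the relative depths are rough. Low values may rest on few reads, and differences of low genes are the least certain.

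The design written before the data were examined foresaw a count test, with limma as its fallback for normalized values; the deposited unit called for the fallback. Genes with a mean of at least 0.5 TPM over the 6 libraries (12507) were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend) on log2(TPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences on the log2(TPM + 1) scale understate the change of low genes. The resistant clones were treated as 4 replicates of resistance against 2 parental libraries (4 residual degrees of freedom, 3.04 prior). A second model had 5 groups, with 1 contrast per clone, an F test of equality of the clones and each clone against the mean of the other 3. It draws its spread from the parental libraries alone (1 residual degree of freedom, 4.32 prior).

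Gene lists were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, with Benjamini-Hochberg adjustment over the lists, and with fry, which tests whether a list's genes move on balance one way, without comparing them with other genes. With fry 6 lists passed, all pointing down: fibroblast (adjusted p = 0.000442), Mullerian (0.0024), Wnt receptors (0.0112), leukocyte (0.0158; median 0.35, with 2 of 4 genes higher and 1 lower), ribosomal (0.0158) and hypoxia and glycolysis genes (0.0345). With an estimated correlation no list passed (every adjusted p was 0.964 or above; the lowest unadjusted p was 0.0581). The lists cover Wnt ligands, receptors, core components, inhibitors and targets; homologous recombination, Fanconi anemia, end joining, PARP enzymes, fork regulators and efflux; interferon, class I and NF-kB genes; epithelial, mesenchymal, Mullerian and stem cell genes; cell cycle, p53, glycolysis, oxidative phosphorylation, cholesterol, stress and NRF2 genes; histones, ribosomal proteins, and leukocyte, endothelial and fibroblast markers. Some lists share members, such as LEF1 and TCF7 (core components and targets) and THY1 (mesenchymal and fibroblast). Calls added up over several lists count such a gene once in each list that holds it. Endothelial markers had too few measured genes for a set test.

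The genes named were, by a rule fixed before the data were examined, the 12 with the largest and the 12 with the smallest log2 difference among genes past the threshold with a mean of at least 5 TPM and all 4 clones on 1 side of both parental libraries; up to 4 called members of each list with the smallest p-values (every called member for the Wnt lists); a few genes of prior interest; and up to 3 called genes per direction with the largest log2 differences between a clone and the mean of the other 3. CDH1, PAX8 and the gene families under other observations were added after their values were seen. A few genes that this rule picked are not reported here. Library totals and composition were compared with exact permutation tests.

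Sharing of calls between clones was set beside 50 simulations of unchanged clones against the same parental libraries. Neighbouring genes were found in the RefSeq annotation of GRCh38.p14, used for names and gene order only: 12070 tested genes (96.5%) were placed and grouped into 795 segments of 15 genes. Each gene's log2 difference was set beside the mean of its nearest tested neighbours (5 on both sides) and of the genes 31 to 50 places away. GC content and length came from the longest GENCODE v29 transcript of each symbol, for 11650 tested genes (93.1%); across genes their Spearman correlations with the log2 difference were -0.053 for GC content and 0.012 for length.

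The models were tested on 5 simulated sets of 12507 genes. Changed genes were drawn only from those with a parental level above about 5 TPM, so recovery among lower genes was not tested. For each clone against parental, every library was simulated with the spread fitted to the parental libraries alone. Recovery for single clones may therefore be too high and is not comparable with that over 4 clones. For resistant against parental, 40.3% of genes changed 1.5-fold, 89.3% changed 2-fold and 98.2% changed 4-fold were recovered; for each clone against parental 54.0%, 98.5% and 100% were. On average 7 unchanged genes were called for resistant against parental and 45 for 1 clone against parental; in sets with no change at all, 0.6 and 20.2 genes were. Alternatives covered other scalings, filters, pseudocounts and empirical Bayes settings, a fold threshold, removal of a GC and length trend, and leaving out each library in turn; counts given without a library are of all calls in that fit. The labels give no batch, and the groups share no replicate numbers.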

Results

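Gene expression was measured by RNA sequencing in PEO1, a BRCA2-mutated human ovarian cancer cell line, and in derivatives of it that grow in olaparib, an inhibitor of the PARP enzymes. The series holds 6 libraries of total RNA: 2 of parental cells (P1 and P2) and 1 from each of 4 resistant clones (C4, C5, C10 and C18). Per the labels the clones were cultured in 2 µM olaparib and no drug is listed for the parental cells. Resistance and exposure to the drug therefore cannot be told apart. The titles call the parental libraries adherent and give no culture format for the clones. A difference in culture format between the groups could therefore not be told apart from resistance either. The labels do not say whether P1 and P2 came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Nor do they say whether the 4 clones arose separately. Genes called over the clones may therefore reflect a shared origin of the clones and not resistance.

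The table lists 17872 genes in TPM, and the values of a library add up to less than the full TPM scale: 305538 and 307895 TPM in P1 and P2, and 298535, 293888, 299548 and 295357 TPM in C4, C5, C10 and C18. Between 16119 and 16418 genes had a value in a library. TPM keep no read total, so the absolute depth behind each value is unknown. Steps between low values gave a rough depth relative to P1. It was 0.955 for P2, 1.21 for C4, 0.953 for C5, 1.03 for C10 and 1.02 for C18. Each of these rests on 34 to 54 of 2357 to 2651 low genes. The total was 306717 ± 1667 TPM (SD, n = 2) in parental and 296832 ± 2653 TPM (SD, n = 4) in resistant libraries, with p = 0.0667 in a two-sided exact permutation test. That is the smallest p that the 15 assignments of 4 against 2 allow, so no single library measure could pass 0.05. Genes above 1 TPM numbered 11391 ± 112 (SD, n = 2) and 11239 ± 46.5 (SD, n = 4) (exact permutation p = 0.0667), and genes with a value 16335 ± 58.0 and 16255 ± 129 (exact permutation p = 0.467). The 10 highest genes held 8.03% ± 0.142 (SD, n = 2) and 7.12% ± 0.421 (SD, n = 4) of the listed TPM (exact permutation p = 0.133), and the 100 highest 26.7% ± 0.0428 and 25.0% ± 0.599 (exact permutation p = 0.0667). Across genes, which are not independent replicates, log2 values correlated at r = 0.992 between P1 and P2, at 0.942 to 0.948 between a parental library and a clone, and at 0.981 to 0.991 between clones. The first principal component held 69.99% of the variance and set the parental libraries apart from the clones; the second held 13.2% and set C4 and C10 (scores 14.6 and 15.4) apart from C5 and C18 (scores -18.3 and -10.8).

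The first comparison set the 4 resistant clones against the parental libraries, to find expression changes that go with acquired resistance. The keratin gene KRT17 rose from 0.787 ± 0.165 TPM (SD, n = 2) to 130 ± 97.1 TPM (SD, n = 4), a log2 difference of 5.89 with a standard error of 0.63 (adjusted p = 0.00101), and its relative KRT34 from 0.297 ± 0.224 to 79.9 ± 47.4 TPM. IER3, an early response gene induced by NF-kB, rose from 2.97 ± 0.582 to 152 ± 20.8 TPM (log2 difference 5.27 ± 0.15 SE), and the cytokine gene IL32 from 10.2 ± 3.59 to 349 ± 26.0 TPM (5.0 ± 0.18 SE). KISS1, which encodes the kisspeptin precursor, rose from 59.6 ± 5.74 to 712 ± 288 TPM, and FLNC, the actin crosslinker filamin C, from 8.91 ± 0.283 to 110 ± 15.4 TPM. The sodium channel subunit SCNN1A fell from 37.8 ± 7.08 to 0.279 ± 0.0363 TPM (log2 difference -4.91 ± 0.12 SE, adjusted p = 4.39e-06). INHBB, the inhibin beta B subunit, fell from 29.998 ± 0.719 to 0.0448 ± 0.0218 TPM (-4.89 ± 0.08 SE), and the surface glycoprotein THY1 from 32.3 ± 1.5 to 0.197 ± 0.0261 TPM (-4.79 ± 0.08 SE).

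The other genes picked as large increases were SUN3, KRT14, the homeobox gene MEOX1, the sialic acid binding lectin SIGLEC15, ASB7 and GNGT2, with log2 differences from 3.49 to 4.33. The other genes picked as large decreases were IGFBP5, which binds insulin-like growth factors, the neuropeptide gene GAL, a gene listed as CEA, the meiotic cohesin subunit REC8, KRT23, RP11-484M3.5, the protease KLK5, the calcium-binding S100A9 and AC005544.1, from -3.36 to -4.56. All 4 clones lay on the same side of both parental libraries in each of these 24 genes, as the rule that picked them required. KRT14 averaged 0.0971 TPM in parental cells and was listed at 99.2 TPM in C4 but 7.64 to 13.1 TPM in the other clones; keratin paralogs share sequence, so their separate levels are uncertain. The KRT14 call was lost without P1 (adjusted p = 0.0815) and without P2 (0.0872), as was that of KLK5 (0.0747 and 0.0542). The AC005544.1 call was lost without P1 (0.0538) and that of GAL without P2 (0.0709).

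**Figure D1:**
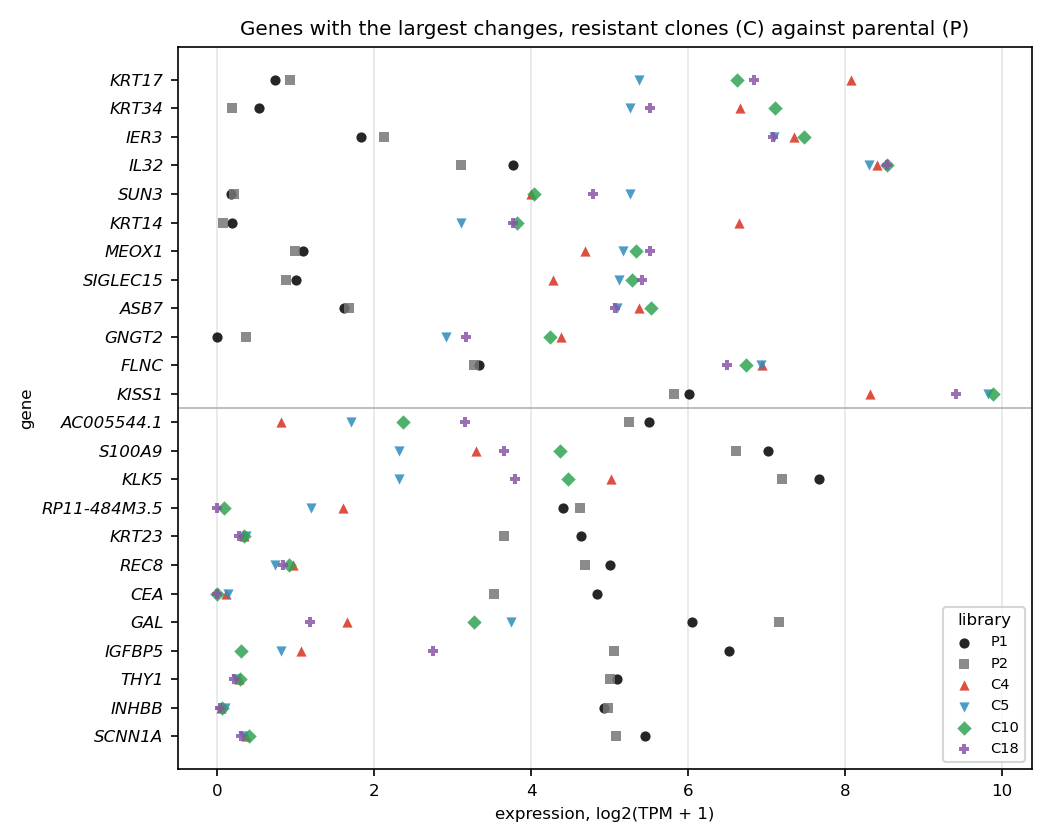
Expression in each library, as log2(TPM + 1), of the 12 genes with the largest increase and the 12 with the largest decrease between parental libraries (P1, P2) and resistant clones (C4, C5, C10, C18), among called genes with a mean of at least 5 TPM and all clones on 1 side of both parental libraries. IER3 averaged 2.97 TPM in parental and 152 TPM in resistant libraries, and SCNN1A 37.8 and 0.279 TPM.

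Across the transcriptome, 2014 of 12507 tested genes were higher and 1989 lower in the clones (4003 in all, 32.0%), and 8504 did not pass the test (limma, Benjamini-Hochberg adjusted). With a log2 difference of at least 1 in size, 252 were higher and 363 lower. The median log2 difference over tested genes was 0.02, and the clones lay wholly above or below both parental libraries in 54.4% of tested genes, against 13.3% by chance. The counts rested on having both parental libraries: without P1 769 genes were higher and 904 lower, and without P2 710 and 956. Of the 4003 calls, 1639 remained without P1 and 1629 without P2, and none changed sign.

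The series title points to Wnt signalling. Of 9 measured ligands and modulators 4 were lower, 0 higher and 5 did not pass (0 higher and 4 lower when adjusted over the list alone). The ligand WNT7B fell from 48.9 ± 7.32 to 22.3 ± 2.65 TPM (log2 difference -1.10 ± 0.14 SE, adjusted p = 0.00189), and WNT7A from 18.8 ± 2.53 to 8.49 ± 2.18 TPM. WNT10A fell from 1.90 to 0.640 TPM, and RSPO4, an R-spondin that sustains Wnt receptors, from 12.5 to 7.32 TPM. Among 13 measured receptors 7 were lower and 0 higher (0 and 8 over the list alone). ROR1, a receptor for WNT5A, fell from 7.57 ± 0.392 to 1.76 ± 0.711 TPM (-1.67 ± 0.23 SE, adjusted p = 0.00251). The R-spondin receptor LGR4 fell from 12.8 to 7.96 TPM, the co-receptor LRP6 by a log2 difference of -0.41, and the Frizzled receptors FZD8, FZD7, FZD1 and FZD5 by -0.31 to -0.54. The receptor list was lower as a set (camera, adjusted p = 0.0195; adjusted p = 0.964 with an estimated correlation), a call also lost among genes with a mean of at least 5 TPM (adjusted p = 0.29). FZD10 was listed at 0.305 ± 0.256 TPM in parental and 0.00636 ± 0.00828 TPM in resistant libraries, below the expression limit of the test.

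Among 22 core components of the beta-catenin pathway 6 were higher and 6 lower (6 and 8 over the list alone). The nuclear partners of beta-catenin moved apart. LEF1 rose from 0.229 ± 0.118 to 2.81 ± 0.669 TPM (log2 difference 1.62 ± 0.16 SE, adjusted p = 0.000785), while TCF7 fell from 9.17 ± 1.18 to 2.81 ± 0.607 TPM (-1.42 ± 0.16 SE). TCF7L2 fell from 12.7 to 6.67 TPM and TCF7L1 from 3.07 to 1.63 TPM. The kinase gene GSK3B, part of the complex that marks beta-catenin for degradation, rose from 19 to 31.4 TPM, with increases of 0.26 to 0.60 for AXIN1, DVL2, CSNK1E and TNKS; GSK3A, TBL1XR1 and CSNK1A1 fell, by -0.24 to -0.40. CTNNB1, which encodes beta-catenin, was listed at 106 ± 2.29 and 88.6 ± 6.96 TPM and did not pass (-0.26 ± 0.09 SE, adjusted p = 0.0628). AXIN2, a feedback target of the pathway, was listed at 0.169 ± 0.0298 and 0.374 ± 0.110 TPM, below the expression limit.

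Inhibitors and target genes went both ways. Of 12 measured inhibitors 2 were higher and 3 lower (4 and 3 over the list alone), and the list's median log2 difference (0.17) and mean (-0.29) differed in sign. The corepressors TLE2 and TLE3 fell, from 5.58 ± 0.400 to 0.612 ± 0.229 TPM (-2.04 ± 0.14 SE) and from 12.4 ± 0.171 to 1.42 ± 0.641 TPM (-2.51 ± 0.23 SE), and the Dickkopf receptor KREMEN2 from 2.92 to 2.23 TPM. The corepressors TLE4 and TLE1 rose, from 2.08 to 4.47 TPM and from 31.5 to 40.3 TPM. Of 24 target genes 6 were higher and 9 lower (8 and 10 over the list alone). The ephrin receptor EPHB3 fell from 6.86 ± 0.226 to 1.22 ± 0.312 TPM (-1.83 ± 0.13 SE) and the transcription factor SOX9 from 10.1 to 3.76 TPM; MSX2, TCF4, MSX1, CD44, NRCAM, JAG1 and TCF7 were also lower. SNAI2, a repressor of epithelial genes, rose from 0.910 ± 0.245 to 6.81 ± 2.64 TPM (1.98 ± 0.27 SE), the AP-1 subunit FOSL1 from 186 ± 35.6 to 439 ± 68.9 TPM, and PPARD from 6.93 to 15.2 TPM; TWIST1 and LEF1 were also higher. The core, inhibitor and target lists did not pass as sets (camera, adjusted p = 0.796, 0.951 and 0.796), nor did the ligands (0.192).

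Across the 5 Wnt lists, the 14 higher and 29 lower calls became 7 and 11 without P1 and 6 and 11 without P2; with 1 clone left out the fits called 10 to 13 and 20 to 28. Among the receptors ROR1 and FZD8 stayed past the threshold without P1, and ROR1 alone without P2. For the lost receptor calls the adjusted p lay between 0.0738 and 0.166. LEF1, TCF7, TLE2, TLE3, TLE4, EPHB3, SOX9, SNAI2, FOSL1, PPARD, MSX2 and WNT7B stayed past it in both cases. The WNT7A call was lost without P1 (0.0838) and the RSPO4 call without P1 (0.195), P2, C4, C5 or C18. Calls for TCF7L2 (up to 0.0943), GSK3B (0.0803) and WNT10A (0.0728) were lost without P1 and without P2, as were those of TNKS, DVL2, TBL1XR1, CSNK1A1, AXIN1, TLE1, KREMEN2, TCF4, MSX1, CD44, NRCAM, TWIST1 and JAG1 (up to 0.291). TCF7L1 was lost without P1 (0.225), and CSNK1E (0.0504) and GSK3A (0.0939) without P2. Leaving out 1 clone also ended calls for FZD1, FZD5, FZD7, DVL2, TBL1XR1, TCF7L1, CSNK1A1, AXIN1, TLE1, KREMEN2, CD44, NRCAM, TWIST1 or JAG1 (up to 0.106), and removing a GC and length trend that for KREMEN2 (0.319).

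**Figure D2:**
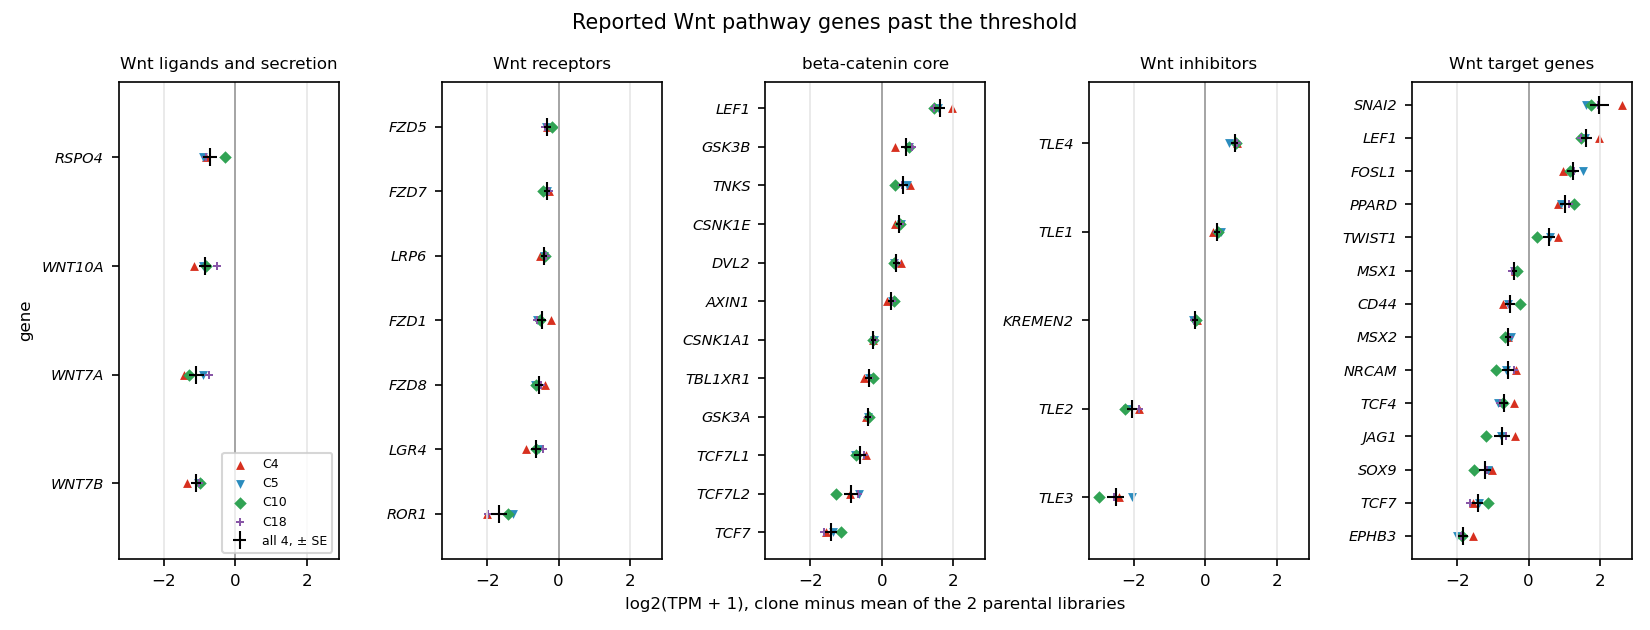
Log2 differences, on the log2(TPM + 1) scale, between each clone (C4, C5, C10, C18) and the mean of the parental libraries for called genes of 5 Wnt lists, with the difference over all 4 clones and its standard error in black. Ligands and receptors lie below 0 (WNT7B -1.10, ROR1 -1.67), while core, inhibitor and target genes lie on both sides (LEF1 1.62, TLE3 -2.51).

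DNA repair genes were of interest because PARP inhibitors act on cells with defective homologous recombination. BRCA2 rose from 0.460 ± 0.0125 TPM (SD, n = 2) to 0.951 ± 0.0759 TPM (SD, n = 4), a log2 difference of 0.42 ± 0.08 SE at low expression (adjusted p = 0.00778), and BRCA1 was listed at 20.3 ± 0.132 and 20.8 ± 0.714 TPM (adjusted p = 0.778). PARP1, the main target of olaparib, rose from 33.8 ± 2.41 to 64.3 ± 14.7 TPM (0.88 ± 0.21 SE, adjusted p = 0.0186). The 15 neighbouring genes around PARP1 had a median difference of -0.01 in C4 and of 0.47 to 0.57 in the other clones. Among 31 homologous recombination genes 5 were higher and 2 lower (5 and 2 over the list alone). RAD51B, a gene of strand exchange, rose from 0.952 to 3.73 TPM and RAD50, of the MRN complex, from 8.85 to 14.4 TPM, while RAD51AP1 fell from 29.9 ± 1.67 to 15.6 ± 0.359 TPM. The genomic segment of RAD51B had a median of 0.72 and that of RAD51AP1 a median of -0.67.

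Of 20 Fanconi anemia genes 2 were higher and 3 lower (0 and 3 over the list alone; median 0.05, mean -0.03). FANCD2, the monoubiquitinated core of the pathway, fell from 8.26 ± 0.0482 to 4.13 ± 0.288 TPM (-0.85 ± 0.09 SE), and the nuclease subunit ERCC1 from 15.9 to 11.9 TPM. Of 20 end joining genes 5 were higher and 3 lower (7 and 3 over the list alone). The Ku subunits XRCC6 and XRCC5 fell, from 281 ± 17.9 to 178 ± 6.89 TPM and from 143 ± 9.24 to 99.4 ± 6.89 TPM, and the polymerase POLM rose from 6.36 to 13.9 TPM. The segment of XRCC6 had a median of -0.59 and that of XRCC5 a median of -0.48. TP53BP1, whose loss is known to restore end resection in BRCA1-deficient cells, was listed at 7.93 ± 0.467 and 9.82 ± 0.577 TPM (adjusted p = 0.0532). Of 22 PARP and base excision repair genes 6 were higher and 4 lower (6 and 4 over the list alone): PARP3 rose from 5.50 to 10.1 TPM and C4orf27, the PARP cofactor HPF1, from 7.57 to 15.3 TPM, in a segment with a median of 0.85, while XRCC1 fell from 17.9 to 11.6 TPM and LIG3 from 8.02 to 5.45 TPM. Of 21 replication fork regulators 4 were higher and 2 lower (4 and 2 over the list alone). The helicase RECQL4 fell from 19.1 ± 1.36 to 5.55 ± 0.424 TPM (-1.62 ± 0.10 SE), in a segment with a median of -0.53. PRIMPOL, which reprimes stalled forks, rose from 2.31 to 5.27 TPM, in a segment with a median of 0.62. Of the 24 repair and efflux genes picked by the naming rule, 11 lay in segments with a median of at least 0.3 in size. So did 67 of the 167 named genes of any kind that lay in a segment, 27.6% of all calls and 1875 of 12070 placed genes. The medians around the other genes were -0.23 to 0.25, with 0.08 for BRCA2, 0.12 for RAD50 and -0.22 for FANCD2.

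Of 8 measured efflux transporters 1, ABCC4, was higher (2.85 to 4.42 TPM) and 0 lower (1 and 0 over the list alone). ABCB1, the P-glycoprotein gene known to export olaparib, was listed at 0.185 ± 0.0188 and 0.0987 ± 0.0718 TPM, below the expression limit. None of the repair and efflux lists passed as a set (camera, adjusted p from 0.624 to 0.951); for efflux, camera pointed down and fry up. Over these 6 lists, the 23 higher and 14 lower calls became 7 and 6 without P1 and 7 and 7 without P2. Calls for PARP1 (adjusted p = 0.0853 and 0.12), BRCA2 (0.0538 and 0.0589), ERCC1 (up to 0.103) and ABCC4 (0.0963 and 0.0542) were lost without P1 and without P2, that of LIG3 without P1 (0.0507) and that of XRCC5 without P2 (0.0567).

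Of 14 measured markers of Mullerian and ovarian cancer cells 10 were lower and 0 higher (0 and 11 over the list alone; median -1.90). The list was lower as a set (camera, adjusted p = 5.01e-06; adjusted p = 0.964 with an estimated correlation). The transcription factor WT1, typical of serous ovarian carcinoma, fell from 8.53 ± 0.348 TPM (SD, n = 2) to 0.0749 ± 0.0945 TPM (SD, n = 4), a log2 difference of -3.15 ± 0.10 SE (adjusted p = 9.56e-06). WFDC2, which encodes the serum marker HE4, fell from 11.8 ± 4.65 to 0.331 ± 0.229 TPM (-3.24 ± 0.24 SE), and the kallikrein proteases KLK7 and KLK8 from 3.56 to 0.194 TPM and from 5.82 to 0.306 TPM. WT1, WFDC2, KLK7 and KLK8 averaged below 0.5 TPM in the clones. They passed the filter only through the parental libraries, which fixed their direction, and the set result rests partly on them. The Mullerian lineage factor PAX8, chosen after its values were seen, was listed at 33.1 and 37.3 TPM and did not pass. Among 27 epithelial genes 10 were lower and 1 higher (1 and 13 over the list alone; median -0.29), and this list was lower as a set too (camera, adjusted p = 0.00823; adjusted p = 0.964 with an estimated correlation). The tight junction gene CLDN3 fell from 14.3 ± 3.62 to 0.763 ± 0.505 TPM (-3.14 ± 0.25 SE), the protease ST14 from 98.6 to 48.3 TPM and the tricellular junction gene LSR from 96.6 to 53.3 TPM. CDH1, the E-cadherin gene, chosen after its values were seen, fell from 16.8 to 5.46 TPM. With fry the epithelial list did not pass (adjusted p = 0.099). Of 26 measured keratins 7 were higher and 2 lower. Among the abundant ones KRT7 rose from 1238 to 1517 TPM, and KRT8, KRT18 and KRT19 did not pass.

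Mesenchymal genes went both ways: of 24 measured, 11 were higher and 5 lower (11 and 6 over the list alone; median 0.35; camera, adjusted p = 0.579; fry pointed down). Fibronectin, FN1, rose from 166 ± 112 to 1566 ± 340 TPM (log2 difference 3.39 ± 0.40 SE) and the matricellular gene CYR61 from 52.5 ± 9.63 to 234 ± 35.4 TPM (2.13 ± 0.17 SE), while TWIST2 fell from 4.56 to 2.21 TPM along with THY1. Of 9 stem cell and ALDH genes 2 were higher and 2 lower (2 and 2 over the list alone): the surface marker PROM1 (CD133) fell from 1.92 to 0.128 TPM, in a segment with a median of -0.86, CD44 fell from 168 to 117 TPM, ITGA6 rose from 34.0 to 67.9 TPM and BMI1 from 15.5 to 20.5 TPM. Of 4 measured leukocyte markers CD14 fell from 3.40 to 0.217 TPM and CD8A and ITGAM rose to 1.29 and 1.16 TPM, 1 lower and 2 higher also over the list alone (median 0.35, mean -0.10; fry pointed down). Of 2 endothelial markers ROBO4 was higher, at 0.542 and 2.11 TPM (1 and 0 over the list alone). Of 6 fibroblast markers 3 were lower and 1 higher (1 and 4 over the list alone): FBLN1 fell from 11.8 to 0.211 TPM, THY1 and FAP also fell, and COL1A1 rose from 1.19 to 2.61 TPM. The stem cell, leukocyte and fibroblast lists did not pass as sets (camera, adjusted p = 0.951, 0.951 and 0.0997); the fibroblast list passed without P2 (0.026) and had 0.964 with an estimated correlation. With fry, which does not compare a list with other genes, the fibroblast and leukocyte lists pointed down (adjusted p = 0.000442 and 0.0158).

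Over these 7 lists the 18 higher and 31 lower calls became 8 and 16 without P1 and 5 and 20 without P2. The 10 lower Mullerian calls became 6 in both cases, and the 10 lower epithelial calls 3 and 6. Calls were lost without P1 for AP1M2 (adjusted p = 0.0761), ITGA6 (0.0722), CD44, BMI1, ITGAM, ROBO4 and FAP, and without P2 for COL1A1 (0.196), CD44, BMI1, ITGAM (0.0571), ROBO4 (0.0825) and FAP; CD44 was also lost without C18 (0.0542), BMI1 without C4, C5 or C10 (up to 0.0769), COL1A1 without C4 or C18 and FAP without C4.

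Inflammatory genes changed in both directions. Of 17 NF-kB target genes 8 were higher and 4 lower (9 and 4 over the list alone; median 0.37; camera, adjusted p = 0.553). The cytokine IL6 rose from 5.55 ± 0.0884 TPM (SD, n = 2) to 18.7 ± 3.46 TPM (SD, n = 4) (log2 difference 1.57 ± 0.17 SE, adjusted p = 0.00107), and TNFAIP3, a feedback inhibitor of NF-kB, from 5.95 to 13.4 TPM. The chemokine IL8 fell from 6.10 ± 0.0191 to 1.36 ± 0.575 TPM and TNFAIP2 from 37.7 ± 6.48 to 9.49 ± 3.35 TPM. With 1 clone left out, 4 to 8 NF-kB target genes were higher and 4 to 5 lower. Of 33 interferon response genes 10 were higher and 5 lower (10 and 5 over the list alone; camera, adjusted p = 0.553, 0.0163 among genes with a mean of at least 5 TPM and 0.964 with an estimated correlation). PARP12 rose from 4.50 ± 0.644 to 13.6 ± 1.26 TPM, IFI35 from 11.8 to 25.7 TPM and the helicase DDX60 from 2.05 to 4.24 TPM, in the segment of C4orf27, while CMPK2 fell from 1.0 to 0.278 TPM. Of 17 class I antigen presentation genes 2 were higher and 3 lower (4 and 3 over the list alone; camera, adjusted p = 0.951): the immunoproteasome subunit PSMB9 rose from 11.4 to 29.1 TPM, while the chaperone PDIA3 fell from 104 to 65.9 TPM, HLA-C from 323 to 231 TPM and CALR from 749 to 608 TPM. Over these 3 lists the 20 higher and 12 lower calls became 11 and 7 without P1 and 8 and 7 without P2. HLA-C and CALR lost their calls in both cases (adjusted p from 0.0604 to 0.143), and CALR also without C18 (0.0604).

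Most cell cycle genes did not pass the test. Of 35 G1/S and replication genes 2 were higher, 6 lower and 27 did not pass (2 and 5 over the list alone; median 0.01, mean -0.05): POLD1 fell from 39.6 ± 1.64 to 25.1 ± 1.39 TPM, the sliding clamp PCNA from 170 ± 8.50 to 117 ± 8.03 TPM and MCM6 from 20.7 to 14.3 TPM, while POLA2 rose from 17.7 to 26.7 TPM. Of 34 mitosis genes 3 were higher, 3 lower and 28 did not pass (3 and 3 over the list alone): ECT2 fell from 33.5 to 20.7 TPM and UBE2C from 150 to 112 TPM, and AURKB and BIRC5 rose, to 73.4 and 109 TPM. Of 23 p53 target genes 3 were higher and 4 lower (3 and 6 over the list alone; median 0.03 with camera pointing down): the stress sensor SESN2 rose from 1.45 ± 0.0430 to 5.15 ± 0.592 TPM and the polymerase POLH from 4.05 to 6.17 TPM, while C12orf5 (TIGAR) fell from 14.1 to 6.93 TPM and FAS from 7.04 to 3.15 TPM. Of 28 unfolded protein and ATF4 response genes 4 were higher and 4 lower (4 and 4 over the list alone; median 0.03, camera down and fry up): ATF3 rose from 1.36 to 4.59 TPM, and CRELD2 fell from 20.2 to 9.78 TPM and HSP90B1 from 227 to 156 TPM. Of 17 NRF2 target genes 2 were lower and 0 higher (0 and 1 over the list alone), PRDX1 from 286 to 192 TPM and GCLM from 5.42 to 3.56 TPM. Of 9 replication-dependent histone genes, whose transcripts lack a poly(A) tail, HIST2H2AC fell from 2.70 to 0.790 TPM and HIST1H2BJ rose from 0.430 to 1.06 TPM (1 and 1 over the list alone). None of these 6 lists passed as a set (camera, adjusted p from 0.624 to 0.951). The 13 higher and 20 lower calls became 4 and 11 without P1 and 5 and 10 without P2. Calls were lost without P1 and without P2 for POLA2 (adjusted p up to 0.0812), AURKB, GCLM (0.227) and HIST1H2BJ (0.159), without P1 for MCM6 (0.0668), BIRC5 (0.0837) and HIST2H2AC (0.0786), and without P2 for POLH (0.0771), HSP90B1 (0.0649) and PRDX1 (0.0815); GCLM was also lost without C10 or C18 and HIST1H2BJ without C18.

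Several glycolytic genes were lower in the clones. GAPDH fell from 3523 ± 240 TPM (SD, n = 2) to 1203 ± 94.8 TPM (SD, n = 4), a log2 difference of -1.55 ± 0.09 SE (adjusted p = 8.94e-05), and TPI1 from 555 ± 45.7 to 237 ± 10.2 TPM (-1.23 ± 0.08 SE). The lactate exporter SLC16A3 fell from 13.7 ± 1.48 to 0.819 ± 0.344 TPM (-3.03 ± 0.18 SE) and ALDOA from 574 ± 35.6 to 371 ± 24.5 TPM. ACTB, another common reference gene, was listed at 1518 ± 56.7 and 1647 ± 288 TPM (adjusted p = 0.622). GAPDH and TPI1 lie in adjacent segments of 15 tested genes each in the RefSeq annotation of GRCh38.p14. In the segment from SCNN1A to MLF2, which holds GAPDH, 15 of 15 genes were lower, 14 of them past the threshold (median -1.08; -1.12, -1.04, -1.14 and -1.01 in C4, C5, C10 and C18), and in the segment from PTMS to C1S, which holds TPI1, 14 were lower (median -1.11). Of 28 hypoxia and glycolysis genes 11 were lower and 2 higher (4 and 12 higher and lower over the list alone; camera, adjusted p = 0.112, which became 0.0484 among genes with a mean of at least 5 TPM and 0.0412 without C10, and 0.964 with an estimated correlation).

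**Figure D3:**
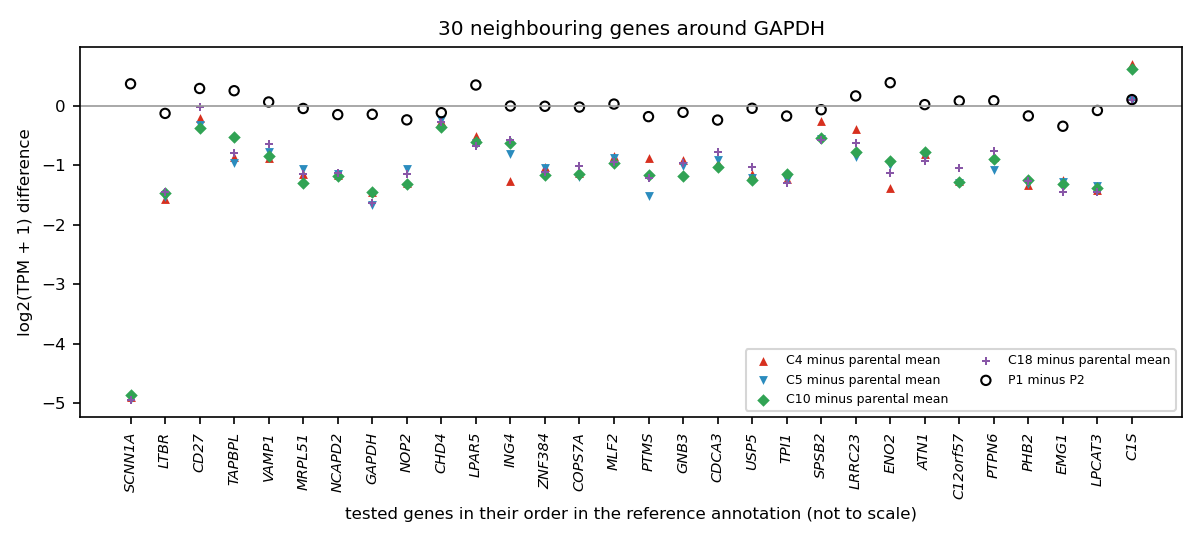
Log2 differences from the parental mean for genes of 2 adjacent 15-gene segments from SCNN1A to C1S, in genomic order, in each clone (C4, C5, C10, C18), with the difference P1 minus P2 for comparison. The median over the first segment was -1.08 for the 4 clones and -0.00 for P1 minus P2.

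Genes of cytosolic ribosomal proteins were lower as a set (camera, adjusted p = 0.00823; adjusted p = 0.964 with an estimated correlation): of 53 measured, 17 were lower and 4 higher (4 and 18 over the list alone; median -0.15). RPL8 fell from 1235 ± 74.6 to 613 ± 34.7 TPM (-1.01 ± 0.08 SE), RPS19 from 382 ± 0.659 to 208 ± 5.45 TPM (-0.87 ± 0.06 SE), RPS16 from 852 to 477 TPM and RPSA from 655 to 381 TPM. The segment of RPL8 had a median of -0.53, with 15 of 15 genes lower; these genes have processed pseudogenes, which makes single levels uncertain. Of 42 nuclear oxidative phosphorylation genes 7 were lower and 1 higher (0 and 7 over the list alone; camera, adjusted p = 0.219): CYC1 fell from 88.8 to 48.2 TPM, in a segment with a median of -0.71, NDUFA9 from 26.8 to 12 TPM, COX7C from 182 to 127 TPM and NDUFA2 from 32.8 to 24.9 TPM. Of 23 cholesterol synthesis genes 8 were higher and 1 lower (9 and 1 over the list alone; camera, adjusted p = 0.202, 0.00837 without P1 and 0.964 with an estimated correlation). INSIG1 rose from 13.8 ± 3.58 to 39.9 ± 3.73 TPM (1.48 ± 0.15 SE), MSMO1 from 7.58 to 16.4 TPM, in the segment of C4orf27, and MVD from 11 to 18.6 TPM, while the regulator SREBF2 fell from 32.5 to 20.8 TPM. Over the 4 metabolic and ribosomal lists the 15 higher and 36 lower calls became 8 and 23 without P1 and 4 and 23 without P2; the NDUFA2 call was lost in both cases (adjusted p = 0.0742 and 0.0567). The 11 lower glycolytic calls became 6 and 7, the 17 lower ribosomal calls 13 and 12, and the 8 higher cholesterol calls 7 and 3.

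**Figure D4:**
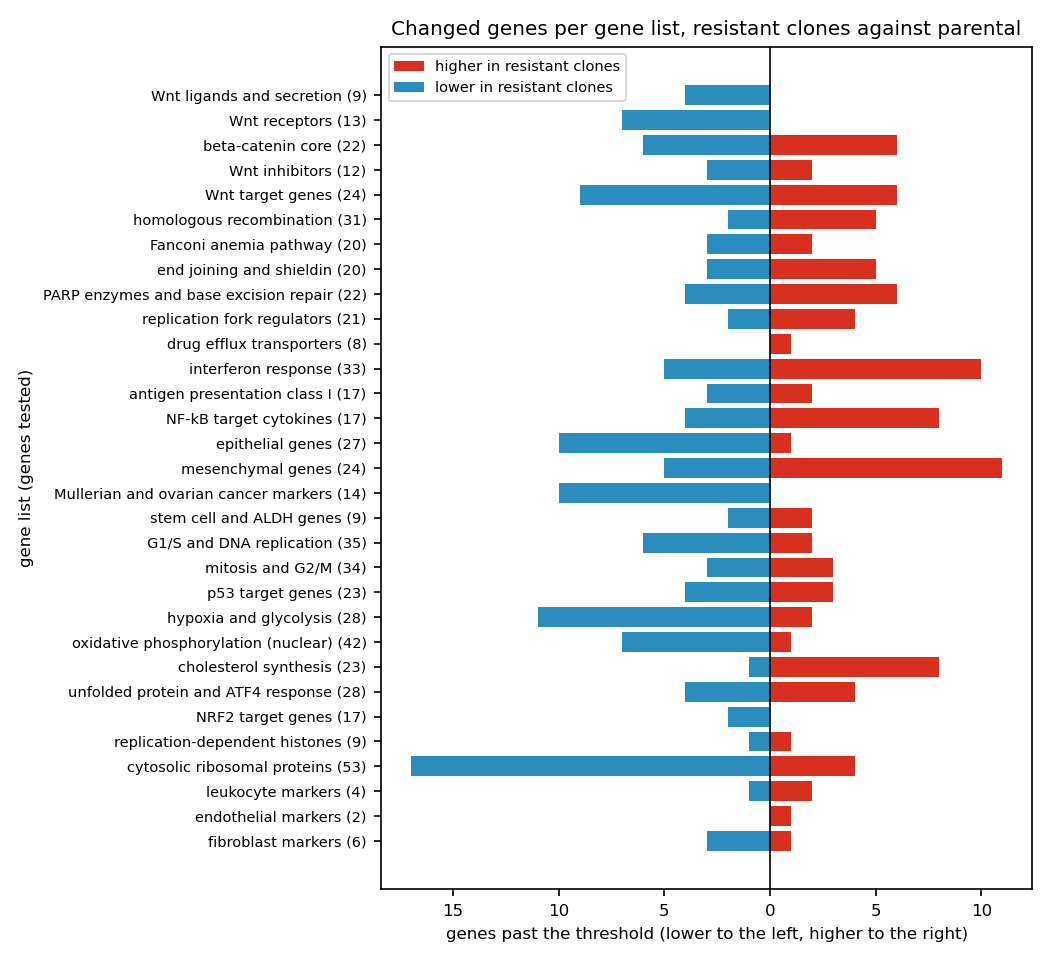
Number of genes called higher and lower in the resistant clones in each gene list, as bars to the right and left. The Mullerian list had 0 higher and 10 lower genes, the epithelial list 1 and 10, and the ribosomal list 4 and 17.

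The next comparison set each clone against the parental libraries, to see how far the derivatives share their changes. C4 had 1277 genes higher and 1395 lower, C5 1392 and 1565, C10 1199 and 1325, and C18 1246 and 1370, of 12507 tested. Called in all 4 clones were 573 higher and 770 lower genes, where independent lists of these sizes would share 1.36 and 2.03, and 50 simulations of unchanged clones against the same parental libraries gave 0.34 and 0.34 on average, with at most 2 and 3. Differences from the parental mean correlated across genes at r = 0.819 (C5 with C10) to 0.918 (C5 with C18), against 0.331 for simulated unchanged clones. Their covariance was 0.270 to 0.302, against 0.00737 simulated, which leaves 0.262 to 0.295. With 2 parental libraries the controls could not be split into sets of at least 2, so part of the excess may come from the shared controls. With 1 clone set against P1 and another against P2, differences correlated at r = 0.715 to 0.875 across genes. Such pairs share no library, which argues against noise of a shared parental library as the whole source of the correlation. These fits have 1 residual degree of freedom, and each lone clone library was assumed to vary like the parental ones. Without the filter on low values no gene was called in any clone (limma; 4884 to 5213 genes per clone at an unadjusted p under 0.05).

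The last comparison asked which genes differed among the 4 clones. KRT14 was highest in C4 (99.2 TPM, log2 difference of 3.08 from the mean of the other 3 clones), as was the cornified envelope gene SPRR1B (109 TPM; 2.1), while glutamine synthetase, GLUL, was low in C4 alone (0.306 TPM, against 12, 14.8 and 7.54 TPM in C5, C10 and C18; -3.21). The chemokine gene CXCL1 was highest in C5 (11.2 TPM, against 1.42, 2.94 and 3.81 TPM in C4, C10 and C18; 1.77), with more in P1 and P2 (37.2 and 31.4 TPM). Each of these values is from 1 library, and the tests took their spread from the parental libraries alone, so they do not show that a clone differs beyond its library. The metallothionein MT1A was at 13 TPM in C10 and at 0.336 TPM in C18 (7.28 and 0.469 TPM in C4 and C5). An F test of equality of the 4 clones called 66 genes, with 1869 at an unadjusted p under 0.05; simulated unchanged clones gave 61.0 calls on average, so the count alone does not show that clones differ. Against the other 3 clones, C4 had 23 higher and 17 lower genes, C5 14 and 18, C10 24 and 11, and C18 6 and 8. With no filter on low values the F test called 0 genes (limma; 2333 at an unadjusted p under 0.05), and among genes with a mean of at least 5 TPM 184.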

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

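The tests of local noise, of shared parental libraries, of a library batch as the whole cause and of a common origin of the clones were chosen only after the results were seen, and that of genes 31 to 50 places away after the neighbour correlation but before its own value.

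Neighbouring genes differed together between resistant and parental libraries: a gene's log2 difference correlated at 0.391 with the mean of its 10 nearest tested neighbours, where 1000 shuffled orders gave at most 0.0368. Chance order, a trend with GC content and length (0.387 after its removal) and local noise that differs from library to library are argued against: segments chosen in 1 clone against 1 parental library gave the sign of at least 75.9% of left-out genes in another clone against the other. The neighbour correlation was 0.0460 for P1 minus P2 but 0.164 to 0.427 between 2 clones, so neighbouring genes also differed together between clone libraries. Gain or loss of chromosome segments in the clones may account for it: with the genes 31 to 50 places away on both sides, beyond adjacent genes, the correlation was 0.234 after that removal (at most 0.0433 in 1000 shuffled orders, 0.0011 for P1 minus P2 and 0.109 to 0.339 between 2 clones). Copy number was not measured here, so shared regulation over long stretches stays open, and keratin and protocadherin clusters also share sequence.

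Genes changed alike in all 4 clones: 1343 genes were called in the same direction in every clone. Shared parental libraries gave at most 5 such genes in 50 simulations of unchanged clones. After removal of a GC and length trend, 75.7% of the 1235 such genes with 5 placed neighbours on both sides had the sign of their neighbours' mean, with at most 56.2% in 1000 shuffled orders. This would argue against a library batch as the whole cause only if a batch acts without regard to gene order. That could not be checked, since no library has a known batch. A single common origin of the clones may contribute: segments chosen in 1 clone against 1 parental library predicted the sign of left-out genes in another clone against the other parental library for at least 75.9% of genes, with 50.3% for shuffled orders. The same segments selected separately in each clone and an effect of olaparib in the medium shared by the clones stay open. A difference in culture format between the groups stays open too. So does a batch as the whole cause or part of it, since the labels give a batch for 0 libraries.

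Of 183 groups of 4 clones examined, 4 had a clone far from the other 3. Chance gives about 1 in 20, which is more, so these 4 are not shown to be true outliers. RSPO4 was high in C10 (9.96 TPM), TLE4 low in C5 (3.86 TPM), FBXO18 low in C10 (14.99 TPM) and FN1 low in C10 (1064 TPM). In 26 genes, such as BGN, CTSB and KRT6A, 1 clone was called higher than parental and another lower, with 1 library per clone. The F test of equal clones called 66 genes, close to the 61.0 of simulated unchanged clones, so this count does not show that clones differ.

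The genes below had the largest log2 differences between 1 clone and the mean of the other 3. Some split the clones into pairs, such as AL139147.1 (0.925 and 1.16 TPM in C4 and C5, 36.2 and 24.4 TPM in C10 and C18), MT1A, H2AFY2, ACKR2 and TMEM213. High and low are against the other clones, and CXCL1 and H2AFY2 were below both parental libraries in all 4 clones. In C4, KRT14 (3.08), BGN (2.81) and SPRR1B (2.1) were high and GLUL (-3.21), AL139147.1 (-2.72) and ACKR2 (-2.45) low. In C5, the chemokine CXCL1 (1.77) and the histone variant gene H2AFY2 (1.61) were high and BGN (-2.83), MAL (-2.68) and AL139147.1 (-2.50) low. In C10, AL139147.1 (2.98), the globin CYGB (2.92) and MT1A (2.47) were high and CPSF4L (-1.93), H2AFY2 (-1.66) and the protease CTSB (-1.61) low. In C18, AL139147.1 (2.24), RP11-761B3.1 (2.13) and ACKR2 (1.89) were high and MT1A (-2.05) and TMEM213 (-1.89) low. BGN, which encodes the proteoglycan biglycan, was at 179 TPM in C4, 8.63 in C5, 63.2 in C10 and 26.5 in C18, with 96.3 and 59.8 TPM in P1 and P2. RP11-761B3.1 was at 751 TPM in C18 and at 129 to 197 TPM in the other libraries. Each of these rests on 1 library per clone.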

How the results depend on the processing

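Chosen only after seeing the data were the other empirical Bayes setting, the filters at 1 TPM and on values in all 6 libraries, the GC and length trend, the pseudocount of 0.1 for clones and lists, and the removal of genes equal in both parental libraries. Under these (where run), both scalings, a pseudocount of 0.1 and no filter, the counts of genes higher and lower in the resistant clones stayed within 1.5 times of 2014 and 1989, and no call changed sign. Exceptions were a log2 difference of at least 1 (252 higher, 363 lower) and a mean of at least 5 TPM, which tests fewer genes (1121 lower). Without 1 library, 710 to 2005 genes were higher and 904 to 1947 lower. Both low ends came from leaving out a parental library (P2 and P1); a lone parental library was then assumed to vary like the clones. Of 174 genes picked by the naming rule, 59 lost their call without P1, 59 without P2, 9 to 21 without a clone, 88 with a log2 difference of at least 1, 13 with no filter and at most 3 under any other setting; 0 reversed. The mean of at least 5 TPM tested 126 of these genes, that of 1 TPM 165, values in all 6 libraries 168 and the GC and length trend 167. Of 4 gene lists past the threshold 0 were left with an estimated correlation, estimated at 0.057 to 0.353 for them against the preset 0.01; without 1 library 4 to 5 passed. A log2 difference of at least 1 left 709 calls for C4, 807 for C5, 709 for C10 and 726 for C18, and 144 higher and 233 lower in all 4 clones. With no filter on low values 0 genes were called for C4, C5, C10 and C18, for either direction in all 4 clones, and by the F test (limma; 5035, 5213, 4884, 4961 and, for the F test, 2333 at an unadjusted p under 0.05). Leaving out the 1005 genes equal in both parental libraries from that set gave 1603 calls for C4, 1914 for C5, 1385 for C10 and 1522 for C18, and 276 higher and 477 lower in all 4; these genes of 0 spread account for part of the loss, and the cause of the rest was not tested. The F test still called 0 there (limma; 1945 at an unadjusted p under 0.05), and 184 with a mean of at least 5 TPM; the cause was not tested. The difference in share of the 10 highest genes (-0.91 percentage points) was -1.75 for the 100 highest. The planned count tests and count scalings (DESeq2, voom and scalings of counts) were not run, since TPM are not counts, and each clone against 1 parental library was not run, as it leaves no residual degrees of freedom. Depth is unknown, which limits what low genes can show.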

Other observations

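The gene families below and the removal of a GC and length trend were chosen after values were seen.

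All 6 measured kallikreins, secreted serine proteases, were lower in the clones: KLK6 fell from 198 to 25.4 TPM (log2 difference -2.96) and KLK10 from 17.6 to 2.61 TPM. KLK7, KLK8 and KLK9 averaged 0.169 to 0.306 TPM in the clones, so they passed the filter only through the parental libraries, which fixed their direction. Whether the 6 kallikrein calls are separate observations or share a shift of their region was not tested. Of 7 metallothioneins, which bind zinc and copper, 4 were lower and 0 higher: MT2A fell from 1472 ± 29.4 TPM (SD, n = 2) to 555 ± 159 TPM (SD, n = 4) (-1.45, adjusted p = 0.0056), MT1E from 441 to 175 TPM and MT1X from 66.1 to 26.0 TPM. In a segment from ITFG1 to MT1A, chosen on every other gene, 14 of the 14 left-out genes were lower (median -0.71). A change of the family was therefore not told apart from a shift of its region. All 4 measured beta-defensins, antimicrobial peptides, were higher, with DEFB4B at 0.228 and 5.27 TPM and DEFB103B at 0.0607 and 4.25 TPM. Their parental means were 0.0572 to 0.228 TPM, so they passed the filter of 0.5 TPM only through the clones, which fixed their direction. The pregnancy-specific glycoprotein PSG4 rose from 1.47 to 19.1 TPM, and 2 of 2 measured members were higher. PSG1, with a parental mean of 0.154 TPM, also passed the filter only through the clones. Of 40 clustered protocadherins, adhesion proteins, 37 were lower and 0 higher. Many members had near-equal values in every library, such as PCDHGA1 and PCDHGA2 (6.20 and 6.12 TPM in P1, 3.20 and 3.20 TPM in C10). The 37 calls are therefore not separate observations. Copies of near-identical sequence in these families make single levels uncertain.

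Adhesion receptors changed in both directions. Of 15 integrins 3 were higher and 4 lower: the fibronectin receptor subunit ITGA5 rose from 17.4 to 53.4 TPM (1.54, adjusted p = 0.0016), while ITGB5 fell from 61.6 to 23.0 TPM (-1.38) and ITGA3 from 185 to 104 TPM (-0.84). Of 11 claudins, tight junction proteins, 5 were lower and 1, CLDN9, higher. Keratins had 7 higher and 2 lower of 26, and S100 proteins 0 and 3 of 12. These counts were the same under median-ratio scaling and scaling to the same total, except that with the same total 8 keratins were higher and 36 protocadherins lower. Without P1 or without P2, 16 protocadherins, 5 kallikreins and 3 beta-defensins were called; 2 keratins were then higher, 1 pregnancy-specific glycoprotein was higher and 1 S100 protein lower, and without 1 clone 21 to 37 protocadherins were lower. Claudins had 3 lower and integrins 1 higher and 3 lower without P1; integrins had 2 higher without P2, and S100 proteins 1 to 4 lower without 1 clone.

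Of 53 genes of cytosolic ribosomal proteins 17 were lower, 4 higher and 32 did not pass, and the list's call as a set was lost with an estimated correlation (camera, adjusted p = 0.964). A trend with GC content and gene length, once removed, gave 21 lower calls, and the median went from -0.15 to -0.19. Median-ratio scaling of the libraries gave 19, and scaling to the same total 16 lower and 5 higher with a median of -0.10. Neither the trend nor these scalings, as tested, could therefore account for the pattern as its whole cause. What stays open is whether growth, drug exposure or neighbouring segments such as that of RPL8 contribute, which was not tested for the list as a whole.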
